A study of Mus musculus with 6 samples.

How the data were processed

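The series holds 6 RNA-seq libraries of mouse metaphase II eggs, 3 matured in vitro (IVM) and 3 in vivo (IVO), grouped by the maturation environment in the labels. No label says whether the replicates came from separate animals or collections, so p-values measure only the spread between these samples, which may be technical. The labels' protocols describe column purification of total RNA with a DNase step and standard Illumina libraries. Strandedness, poly(A) selection, aligner, counting tool and annotation are not given in the sources used here.

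Per the file headers, the authors deposited FPKM, fragments scaled by transcript length and sequencing depth, for each gene and library. Any further scaling between libraries is not stated. Per the file headers, the authors also deposited a p-value and q-values for IVM against IVO and q-values between single libraries. Their smallest p-value was 5e-05. The column of log2 ratios was not used because a spreadsheet had turned part of it into error text, so directions of the authors' calls were taken from mean FPKM. Genes of the authors' table with the largest change were ranked by the ratio of mean FPKM for the same reason.

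The table had 24254 named gene rows, of which 7775 were at 0 in all libraries, and 1 line had been emptied. A spreadsheet had turned 27 gene symbols into dates, of which 26 were restored from their position. Per the submitters' processing notes the build was mm9, but 22992 of 23130 symbols found in the GENCODE release M21 annotation (99.4%) overlapped the gene of that name in GRCm38. Coordinates and gene identifiers printed are those of the GRCm38 annotation, matched by symbol and overlap. A value of 0 is only a listed 0, since it can be a failed estimate.

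Depth is unknown in reads. Relative depth was read from FPKM values under 0.3, which move in steps of what 1 fragment is worth. No count test was run, because FPKM values are not counts, and no interval for counting error can be given.

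Genes with a mean FPKM of at least 1 over the 6 libraries (7746) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists (26) were fixed before the data were examined. Lists with at least 5 members at a mean FPKM of at least 1 were tested with camera against all other tested genes, and with fry. Camera was run with a preset correlation and again with an estimated one. Counts of list members are over those that reached this filter, called measured below. Adjustment for lists was over the 22 lists tested. Library measures were compared by an exact two-sided permutation test of the difference in means, which with 3 against 3 gives no p under 0.1.

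The procedure was tested on simulated data, in 20 simulations of 7746 genes with 200 changed. Of genes changed 4-fold up 98.3% were recovered, 2-fold up 62.2%, to 0.5 of the level 49.9% and to 0.25 of the level 80.0%. False calls were 6.26% of calls, above the nominal level. A planted list was called in 20 of 20 simulations, and 4 of 440 unplanted lists were called. The planted list held only genes raised 2-fold or 4-fold. Simulated noise was independent between genes, so these rates do not show how camera behaves where list members are correlated. Far fewer genes changed in the simulations than were called in the data, so the rates of recovery may not carry over.

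Named genes were chosen by a rule set before the data were examined. It took the 12 largest rises and 12 largest falls among called genes with a mean FPKM of at least 5 and groups that did not overlap. From each list it took up to 4 called members with the largest difference, or the member with the smallest p where none passed. It added Gdf9, Bmp15, Zp3, Mos, Has2, Ptx3 and Tnfaip6, and 3 genes per direction from the authors' calls. Of the genes this rule takes, 1 is not reported here.

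Alternatives covered the pseudocount, the filter, scaling between libraries, the variance model, sample weights, a replicate block, each library left out, thresholds and the authors' own calls. Removal of trends with transcript length and GC content, and the omission of both libraries with the most Ptx3, were added after the data were seen, as were the ranges of abundance under each scaling and the omission of each library from the comparison with cumulus markers. Transcript length was known for 93.2% of tested genes, and 91.0% had an annotated 3′ UTR of at least 100 bases.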

Results

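RNA-seq libraries from mouse eggs arrested at metaphase II, the stage at which an egg is ready for fertilization, were compared between 2 origins. In 3 libraries the eggs had completed meiosis in culture (in vitro maturation, IVM), and in 3 they had matured in the animal (IVO). The question, from the series title, is how maturation in culture alters the transcripts of the egg. The deposited table gives FPKM per gene and library. Summed FPKM was 360308 ± 6077 (SD, n = 3) in IVM and 397295 ± 4177 (SD, n = 3) in IVO. Total read numbers are unknown. Steps between low FPKM values put the depth of the other 5 libraries at 0.78 to 0.91 of that of IVM replicate 1, and depth did not separate the groups (exact two-sided permutation test, p = 0.3).

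More genes were detected in IVM. At an FPKM of at least 1, 7969 ± 100.5 genes (SD, n = 3) were seen in IVM and 7254 ± 70.2 (SD, n = 3) in IVO. The 10 most abundant genes held 17.1 ± 0.282% of summed FPKM in IVM and 19.2 ± 0.281% in IVO (SD, n = 3). The 100 most abundant held 42.9 ± 0.495% and 44.5 ± 0.436%. Each of these measures separated the groups without overlap, and each gave p = 0.1 in the exact two-sided permutation test, the smallest p that 3 against 3 allows. The table used here has no mitochondrially encoded genes.

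Zp3, Khdc3 and Ldhb were more abundant in IVM, and Chsy1 and Lsm14b in IVO. Zp3, which encodes a zona pellucida glycoprotein (ENSMUSG00000004948.12, GRCm38 chromosome 5, 135980099 to 135988624), had an FPKM of 210.5 ± 23.8 in IVM and 16.5 ± 4.12 in IVO (SD, n = 3). Khdc3, a member of the subcortical maternal complex (chromosome 9, 73101836 to 73104438), had 176 ± 10.1 and 11.7 ± 4.77. Ldhb, a lactate dehydrogenase subunit (chromosome 6, 142490249 to 142507957), had 1055 ± 94.9 and 164.6 ± 36.2. In the other direction Chsy1, a chondroitin synthase (chromosome 7, 66109515 to 66173798), had 16.2 ± 1.35 in IVM and 106 ± 7.85 in IVO, and Lsm14b, which encodes an RNA-binding protein (chromosome 2, 180024987 to 180035465), had 282 ± 28.1 and 865 ± 73.2.

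**Figure D1:**
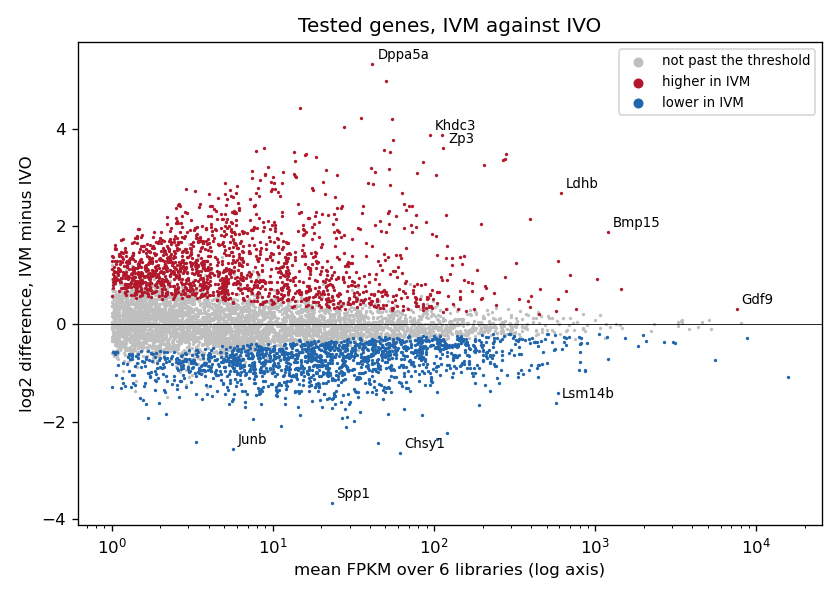
Log2 difference between IVM and IVO, on the log2(FPKM + 1) scale, against the mean FPKM over 6 libraries on a log axis, with 1 point per tested gene. Red points are the 1595 genes higher in IVM and blue points the 1583 genes lower in IVM at an adjusted p under 0.05, and the large positive differences reach 5.32 at Dppa5a.

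Of 7746 tested genes, 1595 were higher and 1583 lower in IVM (limma, Benjamini-Hochberg adjusted p under 0.05), or 41.0% of those tested. Large differences were mostly rises: 869 genes rose and 326 fell by a log2 difference of at least 1, and at a log2 difference of at least 2 the numbers were 172 and 9. The size of this imbalance depended on scaling, with 951 rises and 244 falls of at least 1 under upper quartile scaling and 657 and 424 under quantile normalization. With each library rescaled to the same sum the numbers were 1208 and 273. That rescaling also raised all values, so the added 1 weighed less. Adding 0.1 in place of 1, without rescaling, gave 1072 rises and 471 falls. The 1208 rises therefore cannot be assigned to scaling alone. The imbalance also varied with abundance. Below a mean FPKM of 5, 465 genes rose and 65 fell by at least 1, at 5 to 20 the numbers were 274 and 123, and at a mean FPKM of 20 or more 130 rose and 138 fell. Of all called genes with a mean FPKM of 20 or more, 338 were higher and 836 lower in IVM. Under quantile normalization rises were 1.47, 1.67 and 1.49 times the falls in these ranges, from low to high, so the trend with abundance was not seen there. Groups did not overlap for 4145 genes (53.5%), where chance gives 10% for 3 against 3. The split depended on scaling: with each library rescaled to the same sum, 1917 genes were higher and 1163 lower, and the median log2 difference over all tested genes moved from -0.02 to 0.11. Quantile normalization went the other way, with 1426 higher, 1778 lower and a median of -0.0770. Smaller differences are therefore relative to the scaling used.

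The largest rise was that of Dppa5a, an RNA-binding protein gene of pluripotent cells (chromosome 9, 78367052 to 78368177), from 1.55 ± 2.11 FPKM in IVO to 81.3 ± 17.8 in IVM (SD, n = 3; log2 difference 5.32, SE 0.486, limma with Benjamini-Hochberg adjusted p = 8.38e-05). E330017A01Rik, C130074G19Rik, Tsc22d4, Tmsb10, Cst3, Gm15698, Mis18a and Oas1c also rose, by log2 differences of 3.55 to 4.98. Tmsb10, which encodes an actin-sequestering thymosin, rose from 4.90 ± 1.73 to 104 ± 12.4 FPKM, and Mis18a, a centromere factor gene, from 6.94 ± 2.42 to 103.9 ± 10.7. Values of Oas1c, which belongs to a family of similar genes, are uncertain where reads were shared between copies. Gm15698 had no matching gene in the annotation used.

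Among falls, Spp1, which encodes the secreted protein osteopontin (chromosome 5, 104435118 to 104441050), had the largest, from 41.8 ± 22.4 FPKM in IVO to 4.49 ± 6.67 in IVM (SD, n = 3; log2 difference -3.66, SE 0.795, limma with Benjamini-Hochberg adjusted p = 0.00612). The call of Spp1 was lost with a pseudocount of 0.01 (limma, adjusted p = 0.0546). Its FPKM in IVM replicates 1, 2 and 3 was 12.2, 1.31 and 0. Ticrr, a replication initiation gene, fell from 77.1 ± 17.3 to 13.2 ± 0.892, Tor1a from 176 ± 9.55 to 33.9 ± 5.62, and Rnf185, a ubiquitin ligase gene, from 198 ± 25.5 to 41.1 ± 2.40. Ddhd1, Tmem87a, Srpk1, Nhlrc2, Mier3 and Sptbn1 fell by log2 differences of -2.11 to -1.90.

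**Figure D2:**
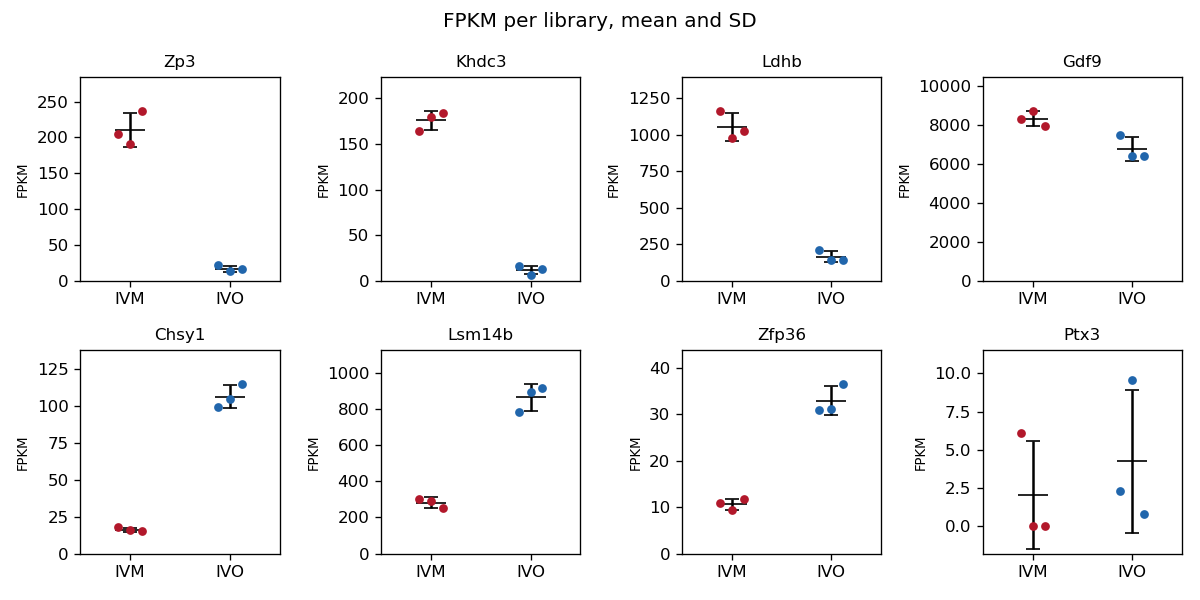
FPKM of 8 named genes in each library, with points for libraries and bars for the mean and SD of each group (n = 3). All genes shown except Ptx3 separate the groups, whereas Ptx3 overlaps, with 6.11 in IVM replicate 1 and 9.59 in IVO replicate 2.

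The oocyte and maternal effect genes rose as a group. Of 34 measured members, 17 were higher, 6 lower and 11 not past the threshold (18 and 6 when adjusted over the list alone; camera adjusted p = 0.000328, and adjusted p = 0.199 with an estimated correlation). Besides Zp3 and Khdc3, the coat gene Zp2 was at 15.2 ± 1.14 FPKM in IVM and 0.398 ± 0.0711 in IVO (SD, n = 3), and Npm2, an egg histone chaperone gene, at 25.5 ± 1.41 and 1.39 ± 0.735. The growth factor gene Bmp15 was at 1869 ± 88.5 and 521 ± 171, and Mos, which encodes the kinase that holds the egg at metaphase, at 1780 ± 35.0 and 1100 ± 285. Gdf9, another growth factor gene, differed by less, 8310 ± 382 against 6746 ± 623 (limma with Benjamini-Hochberg adjusted p = 0.0113), and its call was lost without IVM replicate 2.

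Genes of fertilization and egg activation also rose. Of 16 measured members, 9 were higher and 1 lower (the same numbers when adjusted over the list alone; camera adjusted p = 0.00378, and adjusted p = 0.199 with an estimated correlation). Izumo1r, the egg receptor for sperm, was at 37.0 ± 3.07 FPKM in IVM and 7.10 ± 1.10 in IVO (SD, n = 3). Astl, the protease that modifies the coat after fertilization, was at 642 ± 18.5 and 147.7 ± 43.7, Cd9, needed for sperm fusion, at 9.90 ± 1.89 and 1.29 ± 0.681, and the zinc transporter gene Slc39a6 at 24.7 ± 0.719 and 4.35 ± 0.462.

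Ribosomal protein genes were the third group that rose, with 11 of 27 measured members higher and 2 lower (the same when adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.199 with an estimated correlation). Rpl41 was at 503.9 ± 51.0 FPKM in IVM and 47.1 ± 3.68 in IVO (SD, n = 3), and Rplp1 at 31.1 ± 4.92 and 9.28 ± 1.63. Rps15 and Rpl39 were called too, but their calls were lost in some alternatives. These genes have many pseudogenes, so their values are uncertain where reads were shared. The call of the list was lost when each library's trend with transcript length was removed (adjusted p = 0.148) and when only genes with a mean FPKM of at least 5 were tested (adjusted p = 0.101; range over alternatives 0.000873 to 0.199). The median log2 difference of the list was 0.75, and 0.63 and 0.93 in these settings. Only 27 of the 78 listed genes reached the filter, and without a filter 64 members had a median of 0.39. With the length trend removed the mean over members went from 0.74 ± 0.87 to 0.52 ± 0.83 (SD over 27 genes) and its margin over other genes from 0.64 to 0.44. At a mean FPKM of at least 5 only 10 members were left.

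Immediate early genes, transcribed within minutes of a stimulus in many cells, fell. Of 16 measured members 11 were lower and none higher (also 11 when adjusted over the list alone; camera adjusted p = 0.000328, and adjusted p = 0.237 with an estimated correlation). Junb was at 1.04 ± 1.35 FPKM in IVM and 10.2 ± 4.83 in IVO, Ier3 at 0.395 ± 0.437 and 6.32 ± 1.72, and Zfp36, which encodes an mRNA-destabilizing protein, at 10.6 ± 1.15 and 32.9 ± 3.12 (SD, n = 3). Nr4a1 was at 0.185 ± 0.132 and 2.95 ± 2.27, and its call was lost without IVO replicate 2, without IVM replicate 2 and without IVM replicate 3. The call of the list was lost when only genes with a mean FPKM of at least 5 were tested, which left 7 members with a median log2 difference of -0.57, against -1.05 for all 16.

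Markers of cumulus and granulosa cells, the somatic cells around the egg, moved with the groups in both directions. Of 13 measured members 2 were higher and 3 lower in IVM (2 and 4 when adjusted over the list alone; camera adjusted p = 0.59, and adjusted p = 0.824 with an estimated correlation). Tnfaip6, a gene of the expanding cumulus, was at 0.242 ± 0.419 FPKM in IVM and 2.76 ± 2.07 in IVO (SD, n = 3), with 5.14 in IVO replicate 2, and its call was lost without IVM replicate 3. Inhba and Sdc4 also fell, the latter not past the threshold without IVM replicate 3, while Inha was at 16.9 ± 9.39 in IVM and 3.90 ± 2.84 in IVO and rose. Ptx3 was not past the threshold (limma with Benjamini-Hochberg adjusted p = 0.343), and without IVM replicate 1 it was (adjusted p = 0.0431). Has2 was at 0.886 ± 0.751 and 0.918 ± 0.152, below the filter. Junb, Ier3 and Spp1 had their highest value in IVO replicate 2, at 15.2, 8.27 and 67.6, as did Tnfaip6 and Ptx3. Of the 11 called immediate early genes, 6 had their highest value in IVO replicate 2 and 5 in IVO replicate 3, among the latter Zfp36 at 36.5 and Nr4a1 at 5.21.

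Of the other carry-over lists, 3 of 17 oviduct markers reached the filter: Spp1 and Cdh1 fell and Cldn4 rose. None of 4 stroma and vessel markers passed, and Kdr, with the smallest p, was at 0.906 ± 0.200 FPKM in IVM and 1.68 ± 0.405 in IVO (SD, n = 3). No blood or immune cell marker reached the filter.

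Lists of metabolism went both ways within themselves. Of 32 nuclear genes of oxidative phosphorylation 12 were higher and 3 lower (camera adjusted p = 0.0596), with Cox6a1 at 31.8 ± 5.74 FPKM in IVM and 4.02 ± 1.64 in IVO (SD, n = 3). This list passed without IVM replicate 1, IVM replicate 2, IVO replicate 1 or IVO replicate 3 (adjusted p = 0.0286, 0.0457, 0.0437 and 0.0288; range over alternatives 0.0164 to 0.395). With the length trend removed its margin over other genes went from 0.63 to 0.41 (adjusted p = 0.355). Uqcr10, Uqcrq and Ndufa4 rose by log2 differences of 2.99, 2.77 and 2.37. Of 13 glycolysis and lactate genes 3 were higher and 2 lower (camera adjusted p = 0.604): Ldhb, Pkm and Gpi1 rose, and the glucose transporter gene Slc2a1 fell from 10.9 ± 3.09 to 2.60 ± 0.561. Of 16 genes of pyruvate entry and the tricarboxylic acid cycle 2 were higher and 4 lower (camera adjusted p = 0.604), with Dlst and Aco1 higher and Sucla2 and Cs lower. Citrate synthase, Cs, was at 74.4 ± 5.00 and 135 ± 2.72.

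Of 16 genes of fatty acid oxidation and lipid droplets 2 were higher, Plin3 and Dgat2, and 1 lower, Acsl3 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.604). Of 14 cholesterol synthesis genes 4 were higher and 1 lower (camera adjusted p = 0.524). Fdft1, squalene synthase, was at 15.6 ± 3.88 FPKM in IVM and 1.17 ± 0.563 in IVO (SD, n = 3), Hmgcs1 at 169.9 ± 12.7 and 68.9 ± 24.7, and Insig1, which restrains sterol synthesis, at 121 ± 11.6 and 294 ± 53.1. Of 19 antioxidant genes 7 were higher and none lower (camera adjusted p = 0.296), among them Gpx4, G6pdx, Prdx3 and Gclm.

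Of 24 heat shock and unfolded protein response genes 12 were higher and 5 lower (13 and 5 when adjusted over the list alone; camera adjusted p = 0.0596). This list passed without IVM replicate 1, IVO replicate 2 or IVO replicate 3 (adjusted p = 0.0286, 0.0452 and 0.0324; range over alternatives 0.0187 to 0.395). With only genes of a mean FPKM of at least 5 17 members were left, its median log2 difference went from 0.60 to 0.0383 and its margin in the mean over other genes from 0.63 to 0.67 (adjusted p = 0.101). Hspa5, the chaperone of the endoplasmic reticulum, was at 99.2 ± 7.01 FPKM in IVM and 7.79 ± 1.29 in IVO (SD, n = 3), Calr at 45.4 ± 4.62 and 7.96 ± 1.49, and Hsp90aa1 at 24.8 ± 6.18 and 3.90 ± 2.08. Of 9 hypoxia genes 2 were higher, Egln1 and Bnip3l, and 4 lower, among them Slc2a1 and Ddit4 (2 and 5 when adjusted over the list alone; camera adjusted p = 0.524). Of 16 apoptosis and p53 genes 3 were higher, among them Birc5 and Mcl1, and 3 lower, among them Bcl2l1 and Gadd45a (camera adjusted p = 0.877).

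Of 36 spindle, checkpoint and cohesion genes 10 were higher and 4 lower (camera adjusted p = 0.679), with Tacc3, a spindle pole gene, at 8.59 ± 2.84 FPKM in IVM and 0.591 ± 0.415 in IVO (SD, n = 3); Fzr1, Aurkb and Tubb5 also rose. Of 32 genes of maternal mRNA translation and clearance 6 were higher and 7 lower (camera adjusted p = 0.656): Ybx2 and Pabpc1l rose, while Lsm14b and the deadenylase gene Pan3 fell. Of 27 DNA methylation and chromatin genes 5 were higher and 13 lower (6 and 14 when adjusted over the list alone; camera adjusted p = 0.228). Dnmt1, the maintenance DNA methyltransferase, was at 109.6 ± 8.50 and 21 ± 12, Dnmt3l also rose, the Polycomb gene Suz12 was at 35.5 ± 4.24 and 133 ± 30.9, and Tet3 fell from 1146 ± 207 to 587 ± 25.6.

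Of 31 genes of cAMP and growth factor signalling 6 were higher and 4 lower (camera adjusted p = 0.604). Cdc25b, the phosphatase that starts meiotic resumption, was at 29.5 ± 2.52 FPKM in IVM and 2.04 ± 1.65 in IVO (SD, n = 3), and Mapk3, Akap1 and Egfr also rose. Of 9 embryonic genome activation genes 3 were higher, Arg2, Hspa1b and Dppa2, and 1 lower, Klf17 (camera adjusted p = 0.228). Of 19 proteasome genes 5 were higher, among them Psmb5, Psmc6 and Psmb2, and 3 lower, among them Psmd7 (camera adjusted p = 0.877). Of 25 autophagy and lysosome genes 8 were higher, among them Map1lc3a, Npc2, Ctsd and Ctsb, and 2 lower (camera adjusted p = 0.184). Of 31 core histone genes 7 were higher and none lower (camera adjusted p = 0.269), among them Hist1h2be, Hist1h2bc, Hist1h2bg and Hist1h2bl, near-identical copies whose values are uncertain. With only genes of a mean FPKM of at least 5, which left 5 members, the histone list passed (adjusted p = 0.0181; range over alternatives 0.0181 to 0.854). With the length trend removed its median went from 0.25 to 0.0146 and its margin over other genes from 0.25 to -0.0856 (adjusted p = 0.854).

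The calls of Cdh1, Klf17, Dgat2, Gadd45a, Gpi1, Ctsb and Hist1h2bg were each lost in 6 to 10 alternatives, some of which left out a single library. Where no other numbers are given, the numbers adjusted over the list alone were the same. The apoptosis and spindle lists had medians of -0.0401 and -0.0667 but means of 0.10 and 0.21, and the camera direction was that of the means. The stroma and vessel list had a median of 0.0266 and a mean of -0.0169. In all, 4 of 22 lists with at least 5 measured members passed the camera test with the preset correlation, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). The estimated correlation was 0.0176 for the oocyte list and 0.0912 for immediate early genes, above the preset one. For the egg activation and ribosomal lists it was -0.0567 and -7.35e-05, below the preset one. A higher correlation therefore does not explain why the calls of the egg activation and ribosomal lists were lost. By fry, which asks of each list alone whether its genes move, 14 lists moved on balance in one direction and 22 changed in either direction. With 41.0% of all tested genes called, a change in all 22 does not set these lists apart from other genes.

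The authors' deposited table marks 3685 genes at a q under 0.05, of which 1870 have a higher and 1815 a lower mean FPKM in IVM. Of the genes tested here, 1433 were called higher and 1477 lower in both, 0 in opposite directions, 268 here only and 552 in the authors' deposited table only. Among those called here only were Spp1, Uqcr10, Ndufa4, Gpx4, Arg2, Psmb2, Rps15 and Rpl39. By the ratio of mean FPKM, the marked genes with the largest rise were C130074G19Rik, Tmem80 and Dppa5a, and those with the largest fall were Itm2a, Gas1 and Ier3. In the limma test the call of Itm2a was lost without IVM replicate 1, IVM replicate 3 or IVO replicate 2 (adjusted p = 0.0537, 0.0673 and 0.0601; range over alternatives 0.000774 to 0.122), and Tmem80 was below the filter.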

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

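No gene that the rule for named genes took and that was tested changed direction in any alternative that tested it. Has2 and Tmem80 were below the filter and have no test. The tests that leave out both libraries with the most Ptx3 or remove length and GC trends were chosen after the data were seen. With only genes of a mean FPKM of at least 5, 835 were higher and 1392 lower in IVM, or 37.5% higher. Of the 3241 genes this leaves out, 780 were called higher and 228 lower in the main analysis. At an adjusted p under 0.01 the numbers were 1019 higher and 1009 lower, and with a log2 difference of at least 1 they were 869 and 326, by construction. Without both libraries with the most Ptx3, 1035 were higher and 916 lower, with fewer samples. Leaving out 1 library gave 1205 to 1634 higher and 1177 to 1617 lower genes, 4 to 6 lists, and 681 to 773 more detected genes in IVM. With the estimated correlation 0 lists passed, against 4.

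The camera direction of lists with no call turned in 10 cases, and the cause was not tested. The median changed sign in 4 of them and not in 6. Without a filter the medians were 5.43e-06 for glycolysis, -0.0459 for apoptosis, -0.00661 for cAMP signalling and -0.00285 for cumulus markers. At a mean FPKM of at least 5 they were -0.0540 for maternal mRNA clearance, -0.23 for the proteasome and 0.19 for cumulus markers. Maternal mRNA clearance had 0.0228 under quantile normalization, and the proteasome 0.0794 without IVO replicate 1 and 0.0101 with the length trend removed. The median of the proteasome list ranged from -0.15 to 0.22 when 1 library was left out. Over all alternatives 25 medians of 9 lists, none of them called, changed sign. Examples are glycolysis (-0.0631 without IVM replicate 3), cholesterol synthesis (-0.0338 at a mean FPKM of at least 5), and apoptosis (0.0998) and spindle genes (0.0727) with each library rescaled to the same sum.

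With replicate number as a block, 1626 genes were higher and 1558 lower, and 6 lists passed, among them oxidative phosphorylation (adjusted p = 0.0411) and heat shock (0.0358), which otherwise had 0.0596 each. Whether the numbers pair the samples cannot be told. Deviations of same-numbered libraries correlated at 0.0777, 0.0599 and 0.09, against -0.112 to 0.0470 for different numbers. Each sample thus correlated best with its own number, but all these values are low. Deviations were taken from group means, so higher values for the same number push the others down, and the contrast is partly built in. The count test was not run because the values are FPKM, and the setting without mitochondrial genes was not run because the table used here has none. Depth limits low genes.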

Other observations

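Outside the fixed lists, families of genes that share a symbol stem were scanned after the data were seen. Of 100 families with at least 8 tested members, none was over-represented among higher or lower genes after Benjamini-Hochberg adjustment (Fisher's exact test). The smallest adjusted value was 0.0857, for the tyrosine phosphatase stem Ptpn (0 of 8 higher, 6 lower) and for Arhgap (2 of 16 higher, 9 lower).

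The tests of depth, the polyadenylation element and cumulus cells below were chosen after the result was seen. The excess of large rises over large falls in IVM was set against 3 technical explanations, and no biological explanation was tested. Before any trend was removed, 869 genes rose and 326 fell by a log2 difference of at least 1. After each library's trend with transcript length was removed the numbers were 839 and 329, and after removal of the GC trend 853 and 336. The excess thus stayed after removal of either trend. Of the 810 rises with a known length, 98.1% and 99.8% stayed called. Removal moved genes by a median of only 0.0391 and 0.0367, against a median rise of 1.45, so this share could hardly fall. At a mean FPKM of 5 to 20, rises were 2.23 times the falls (exact 95% interval 1.79 to 2.78, which treats genes as independent). Under the other scalings they were 1.67 to 3.51 times the falls. The excess was thus not limited to the lowest genes, but the bounds were set after the counts were seen, so this does not exclude depth. Rises were 5.72% of genes at a mean FPKM of at least 20 (exact 95% interval 4.80 to 6.76). With 130 rises and 138 falls there, this share says nothing about the excess. Below 5, rises were 7.15 times the falls and depth stays open, since genes near the floor decide nothing. A first test used only genes at a mean FPKM of at least 20, where rises were 0.942 times the falls, as depth would give (1.49 under quantile normalization and 1.72 with each library rescaled to the same sum), and was replaced by these parts, whose bounds were set after their counts had been seen.

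Which genes rose and which fell differed in the cytoplasmic polyadenylation element, a 3′ UTR signal that controls tail length during maturation. Of genes that fell by a log2 difference of at least 1, 30.5% carried it in the last 100 bases, against 11.6% of those that rose. The pooled odds ratio over quartiles of 3′ UTR length was 3.31 (95% interval 2.35 to 4.66), and over all called genes 2.15. The contrast was not even over the quartiles. In the lowest quartile of length, 9.85% of called higher and 34.41% of called lower genes carried the element. In the highest quartile the shares were 18.01% and 23.77%. Neither ratio was adjusted for abundance, and 465 of 869 rises but 65 of 326 falls lay below a mean FPKM of 5. Hexamers of the same bases in another order gave an odds ratio of 1.09 (0.735 to 1.61) in stretches without the element. Over all called genes they gave 1.45 (1.19 to 1.78). Leaving out stretches with the element took the falls from 311 to 216 and the rises from 777 to 687. Because this removed more of the falls, the control cannot exclude base composition. Genes not past the threshold carried the element at 25.5%, so the contrast is mainly a lack of it among rises. Clearance of messages, tail length, capture of tails in library preparation and lagging eggs were not tested.

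The fall of immediate early genes may come from cumulus cells left on eggs matured in vivo, and this cannot be told apart from a difference in the eggs. The median excess in IVO of the 11 called members was 0.847 times the largest excess of any cumulus or granulosa marker, that of Gja1, and 5 of the 11 exceeded it. The excess of Gja1 came from IVO replicate 2: without that library it was -0.883, the largest was that of Ptgs2, the ratio was 2.19 and 10 of the 11 exceeded it, while without IVO replicate 3 the ratio was 0.549. An earlier version of this test set 2 genes, Dusp1 and Zfp36, against 4 markers and gave 7.28, but both were picked for their values and it was replaced by the whole lists. The list kept its camera call without IVO replicate 2 (adjusted p = 0.00123; range over alternatives 7.82e-07 to 0.237).

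The larger number of detected genes in IVM held at an FPKM of 5, where the lowest IVM library had 98 more genes than the highest IVO library. This argues against depth as the whole cause. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3178 genes (3849 at an unadjusted p under 0.05) and the highest other split 0 by limma (157 at an unadjusted p under 0.05), and 1 of the 10 splits gave as many. For lists the real split gave 4 and the highest other split 4, so 2 of the 10 splits gave as many.

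In the authors' deposited table, 12 genes had a q under 0.05 between IVO replicates 1 and 2 and 8 between IVO replicates 1 and 3, against 0 between IVO replicates 2 and 3 and 0 in each pair of IVM libraries. The ribosomal RNA precursor Rn45s ranged from 147 FPKM in IVO replicate 1 to 632 in IVO replicate 3.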
